A study of Mus musculus with 8 samples.

How the data were processed

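Gene expression was measured on Affymetrix arrays in luminal cells of the mouse mammary gland, the epithelial cells that line the ducts and alveoli and make milk. Per the labels' protocols, fresh tissue of 15-day-pregnant mice was digested with enzymes, stained and sorted by flow cytometry. RNA was purified on Qiagen columns, and 500 pg of total RNA per sample was amplified and labelled with biotin with the Ovation Pico WTA V2 and Encore Biotin kits. The series design gives 4 biological replicates of control cells and 4 of a3a6KO cells. The KO name refers to the alpha 3 and alpha 6 integrin chains, encoded by Itga3 and Itga6. Groups were taken from the cell subtype label of each sample. The titles of the 4 a3a6KO samples begin with DKO but also carry the word Ctrl, whereas their source name, like the subtype label, names only the knockout. The groups therefore stand as labelled. What was deleted in either gene, which Cre line was used and how the mice were bred are not given in the sources used here.

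The deposited values are on the log2 scale, 1 per probe set and array, and per the submitters' processing notes they were made with Affymetrix Expression Console and RMA, with no versions stated. RMA corrects background, normalizes the arrays to 1 distribution by quantiles and summarizes the probes of a set. The quantile step makes the arrays alike, so a shift shared by most genes would be removed from these values. The deposited log2 values ran from 0.96 to 13.28, and the median over genes of single arrays lay within 0.021 of the mean of these medians. They were tested as deposited, with no further normalization and no pseudocount.

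Probe sets were named through GEO's platform annotation. Of 28846 probe sets, 19572 had 1 gene symbol, 0 had several and 9274 had none. The unnamed sets comprised 2634 transcript sets and 6640 control sets, among them 5222 intron and 1324 exon control sets. Where several sets shared a symbol (55 genes), the set with the highest mean over all arrays was kept, and the log2 differences of such sets had opposite signs in 17 of the 55. This left 19505 genes. The 19572 symbols were the same as those of the RefSeq gene table, matched through the gene identifiers. No coordinates are given because the genome build behind the probe sets is not named.

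Depth has no counterpart on arrays, and the number of arrays limits the precision. The median standard error of a log2 difference was 0.234, and the median 95% interval reached 0.53 to either side, a 1.44-fold change. The area under the curve that separates exon from intron control sets, a measure of signal over background, was between 0.852 and 0.879. On single arrays, the intron control sets had medians of 2.85 to 3.07 and 95th percentiles of 6.38 to 6.9. Of the genes, 2244 to 3229 lay above that array's 95th percentile, so many genes were measured within the range of the intron sets. A gene under that percentile can still lie above most intron sets. A gene named below without a remark on background need not exceed that percentile on every array. No 2 arrays held identical values. Correlations over genes were 0.930 to 0.945 within groups and 0.924 to 0.946 between groups.

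The comparison of a3a6KO with control used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, all 8 arrays, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Adjusted p-values of single genes in the report come from this limma fit. Genes were also counted with a fold change of at least 1.5. Before the data were examined, 32 gene lists were fixed from textbook knowledge, with 659 genes between them, of which 592 were measured, 2 of them through an updated symbol. Lists with at least 5 measured members were tested with limma's camera, which asks whether the genes of a list differ from the other genes, at its preset correlation of 0.01 and adjusted over the 30 lists tested. The mitochondrial genome list had no measured member, and the target integrins were only 2 genes. Camera with an estimated correlation was run beside it, and so was fry, which tests whether the genes of a list move 1 way on balance (directional) or in either direction (mixed). A list score was the mean over its members of the log2 value minus the gene's mean over all arrays. Scores were compared by an exact permutation test over the 70 assignments of samples to groups, two-sided, whose smallest possible p is 0.0286. Members of a list were also counted with p adjusted over the list alone.

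The genes named in the text were chosen by a rule fixed before the data were examined. It took Itga3 and Itga6, the 10 largest rises and falls among genes past the threshold, or the 5 genes of smallest p in each direction where none passed, up to 4 members of smallest p of each list described, and Csn2, Wap, Lalba, Elf5, Stat5a, Cdkn1a, Mdm2, Mki67, Krt14, Krt8, Itgb1 and Itgb4. Predicted genes, 2390 in number, were skipped among those of smallest p.

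The tests were tried on simulated data, which had the spread of these arrays for limma only. Over 19505 simulated genes, limma found 24% of 50 genes changed 2-fold, 84% of those changed 4-fold, 90% at 8-fold and 94% at 16-fold, with 14 false calls, and 0 calls where nothing was changed. Among 3000 simulated genes, camera's preset correlation wrongly called an unchanged list of 14 genes in 3% of 100 runs without correlation between its members, in 17% at a correlation of 0.1 and in 37% at 0.3. With an estimated correlation these shares were 0%, 1% and 8%.

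Alternatives were leaving out each sample in turn, the replicate number as a block, another quantile normalization, centring of each array on its median, leaving out genes under the 40th percentile of mean level, a variance trend with robust estimation, array weights, the mean of a gene's probe sets, every probe set as a feature, the other list tests, and the rank of a list's median among 10000 random lists of like expression. Fits without samples of high marker scores and fits with a marker score as a covariate were added after seeing the data.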

Results

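The series holds 8 arrays of sorted luminal mammary cells from mice on day 15 of pregnancy, 4 labelled control and 4 labelled a3a6KO. Integrin chains alpha 3 and alpha 6 pair with beta chains into receptors for laminin, a protein of the basement membrane. The comparison asks how luminal cells labelled as knockouts of both chains differ in gene expression from control cells while the gland prepares to secrete milk. The name a3a6KO stands for the samples so labelled, whose titles also carry the word Ctrl. All differences below are log2 values of a3a6KO minus control.

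The targeted genes were lower in the a3a6KO samples, and unevenly so. Itga6 was at 8.88 ± 0.18 in control and 6.42 ± 2.09 in a3a6KO (log2, SD, n = 4), a difference of -2.46 (SE 0.855), which was -1.54 without a3a6KO 2. Its 4 control values were 8.83, 8.73, 9.14 and 8.80, and its a3a6KO values 5.95, 3.65, 8.21 and 7.85. Itga3 was at 6.42 ± 0.80 in control and 5.15 ± 0.58 in a3a6KO, a difference of -1.26 (SE 0.42). It exceeded the 95th percentile of the intron control sets of the same array, taken as background, on 1 array, control 4. Its levels thus lay mostly within the range of the intron sets, though above their medians (2.85 to 3.07), and no fold is given. The control values of Itga3 were 6.72, 6.30, 5.37 and 7.27, and its a3a6KO values 5.11, 4.34, 5.55 and 5.60, so control 3 lay below a3a6KO 3 and 4. Itga6 exceeded background on all 4 control arrays and on a3a6KO 3 and 4. Neither gene passed over all genes (adjusted p = 0.944 for each), and both passed when adjusted over the list alone, the list being these 2 genes (adjusted p = 0.0177). In exact permutation tests, Itga6 gave p = 0.0286, the smallest possible, and Itga3 p = 0.0857. Both calls were lost with the basal keratin score as a covariate (Itga3 -1.30, adjusted p = 0.138, and Itga6 -1.31, adjusted p = 0.278), and that of Itga6 without control 2 and 3 (-2.40, adjusted p = 0.0783). The basal keratin score itself differed between the groups by -1.53 (exact permutation p = 0.0857), so the fit with that covariate cannot separate the score from the genotype. The difference of Itga3 was not reduced in that fit. Where the probes lie relative to the deleted parts is not known here, so a level that stayed high in an a3a6KO sample does not show an intact gene, and the values of a3a6KO 3 and 4 do not show a loss of both chains. The beta chain gene Itgb1 differed by 0.17 (SE 0.233), less than the spread between replicates, and Itgb4 by 0.07 (SE 0.524) and by -0.52 without control 3, but Itgb4 exceeded background on 0 arrays, so its difference does not tell whether it changed.

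**Figure D1:**
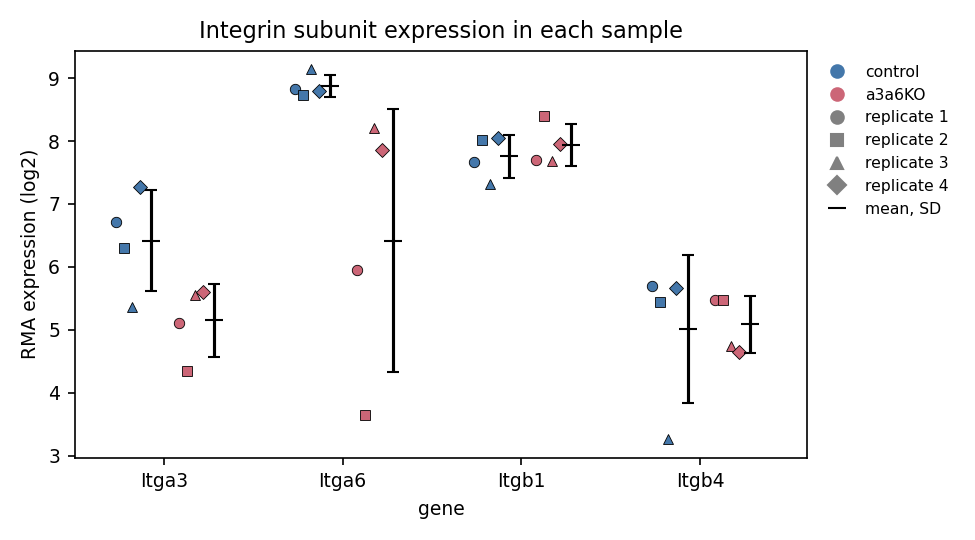
RMA log2 expression (y axis) of 4 integrin genes (x axis) in each sample, with 1 point per sample, its shape giving the replicate, and black bars for the group mean and SD. All 4 a3a6KO samples lie below the controls for Itga6, where a3a6KO 3 (8.21) and 4 (7.85) stayed close to the controls and a3a6KO 2 lay at 3.65.

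No single gene passed the threshold between a3a6KO and control. The lowest p-values belonged, among genes lower in a3a6KO, to Abcg4, a transporter gene (-1.11), Ehhadh, which encodes an enzyme of peroxisomal fatty acid oxidation (-2.01), the clock repressor gene Nr1d1 (-1.52), Mpp1 (-1.66) and Slc38a10 (-2.88). Among genes higher in a3a6KO they belonged to Klhl5 (1.79), Prpsap1 (2.15), Ehbp1 (0.95), Crtap, which takes part in collagen modification (1.90), and Commd2 (1.54). In each of these 10 genes, all 4 values of one group lay outside the range of the other, yet their adjusted p-values ran from 0.631 to 0.743 in limma. The limma fit called 0 of 19505 genes, with or without a minimum fold of 1.5, and 1000 genes had an unadjusted p under 0.05, of which 468 were higher and 532 lower, against 975 by chance. Prpsap1 and Abcg4 exceeded background on 0 arrays, Klhl5, Ehbp1 and Crtap on 0 control arrays, and Ehhadh, Nr1d1, Mpp1 and Slc38a10 on 0 a3a6KO arrays, so the sizes of these 9 differences are uncertain. Groups did not overlap in 573 genes (2.94%), where chance gives 2.86%. Of simulated genes with a 2-fold change, 24% were found, and of those with a 4-fold change 84%. The simulation gave dim genes the full change too, and changed genes of all sizes together. These shares may therefore be too high for real genes near background or where few genes change.

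Milk protein genes were lower in a3a6KO as a group, by small amounts. All 14 measured members had lower means in a3a6KO, with a mean difference of -0.37, or 1.29-fold, and 12 of them exceeded background on every array. The list score was 0.18 ± 0.13 in control and -0.18 ± 0.15 in a3a6KO (SD, n = 4), and each a3a6KO score lay below each control score. The mucin gene Muc1 (-0.74, SE 0.256), the lactose synthase subunit gene Lalba (-0.74, SE 0.306), Lao1, which encodes an L-amino acid oxidase of milk (-0.78, SE 0.328), and the whey protein gene Wap (-0.58, SE 0.258) had the lowest p-values. The casein gene Csn2, near the top of the measured range, differed by -0.14 (SE 0.148), less than its standard error. Of the 14 genes, 0 passed over all genes and 0 adjusted over the list alone (smallest adjusted p = 0.141). Camera called the list lower (adjusted p = 3.46e-05), a call lost at adjusted p = 0.779 with an estimated correlation. The score differed by an exact permutation p of 0.0286, the smallest possible, which became 0.429 when adjusted over the 30 lists and was 0.0571 without control 1 or control 4.

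Genes for lactose synthesis and nutrient transport were lower in a3a6KO in 16 of 19 members, with a mean difference of -0.29 (-0.19 without a3a6KO 2). Examples were B4galt1, the galactosyltransferase of lactose synthesis (-0.86, SE 0.275), above background on every array, and the phosphate transporter gene Slc34a2 (-1.51, SE 0.509), above it on 0 a3a6KO arrays. Others were the amino acid transporter gene Slc6a14 (-0.41, SE 0.196) and the water channel gene Aqp5 (-0.50, SE 0.284), both below background on every array. Of the 19 genes 0 passed over all genes and 0 adjusted over the list alone (smallest adjusted p = 0.145). Camera called the list lower (adjusted p = 0.00901), and the call was lost at adjusted p = 0.779 with an estimated correlation, at 0.150 without a3a6KO 2 and at 0.149 with the basal keratin score as a covariate, where the mean was little altered (-0.27).

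**Figure D2:**
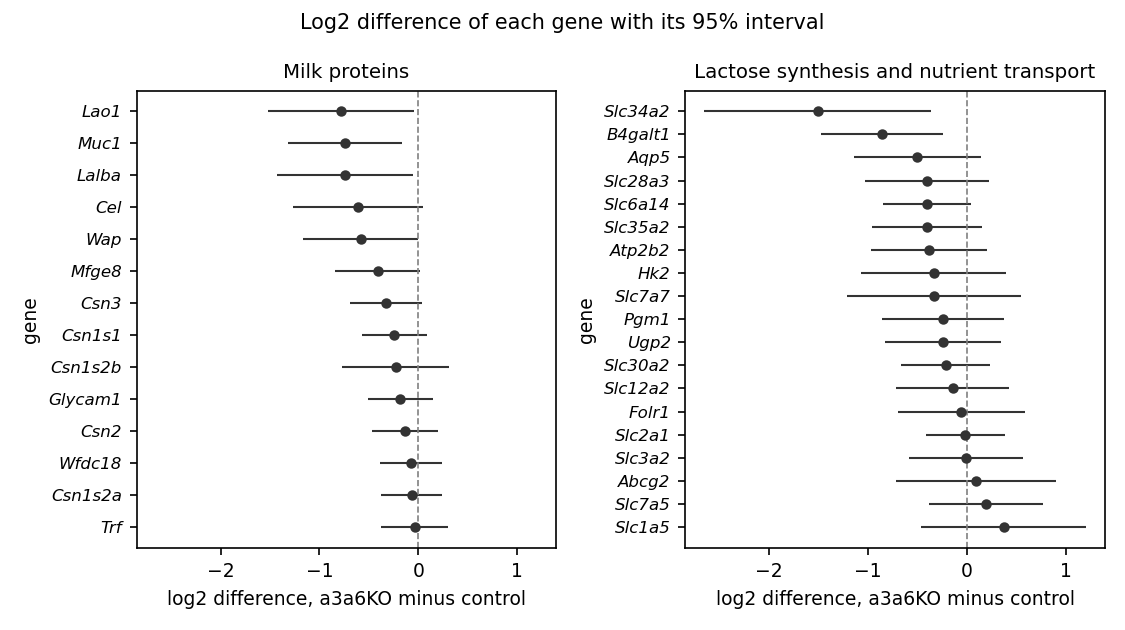
Log2 difference of a3a6KO minus control (x axis) for each measured gene (y axis) of the milk protein list and of the list of lactose synthesis and nutrient transport, with points for the estimate from 4 samples a group and lines for its 95% interval. All 14 milk protein genes lie below 0, from -0.78 to -0.04, and most intervals include 0.

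The lipid and prolactin programmes of the secretory cell showed no shift past the threshold. In the milk lipid list, 15 of 26 genes were lower (mean -0.12), with 0 past the threshold over all genes and 0 adjusted over the list alone. Thrsp, a regulator of fatty acid synthesis, differed by -0.50, Lpin1 by -0.63, the desaturase gene Fads2 by 0.31 and the fatty acid binding protein gene Fabp3 by -0.30. Camera gave an adjusted p of 0.438, the mean was -0.042 without a3a6KO 2, and the list was called lower only without a3a6KO 4 (mean -0.22, adjusted p = 0.0469). In the prolactin and Stat5 list, 8 of 16 genes were higher and 8 lower (mean -0.14, or -0.019 without a3a6KO 3 and -0.21 without a3a6KO 2, camera adjusted p = 0.532), with 0 passing over all genes and 0 adjusted over the list alone. Its lowest p belonged to Cish, a feedback inhibitor gene induced by Stat5, at 7.89 ± 0.35 in control and 6.72 ± 0.72 in a3a6KO, a difference of -1.17 (SE 0.348). Adjusted over the list alone, limma gave Cish an adjusted p of 0.127. Akt1 differed by -0.62, Jak2 by 0.29, the alveolar transcription factor gene Elf5 by -0.30 (-0.16 without a3a6KO 1) and Stat5a by -0.31 (-0.52 without control 1 and -0.07 without a3a6KO 3), none past the threshold.

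Cell cycle genes were slightly higher in a3a6KO, in 21 of 37 members and by 0.22 on average, but 27 of the 37 exceeded background on no array. Kif20a, which encodes a kinesin of cell division, was at 2.87 ± 0.47 in control and 4.09 ± 0.20 in a3a6KO (SD, n = 4), a difference of 1.22 (SE 0.243), below background on every array. Cenpf, a kinetochore gene, differed by 0.91, and the replication genes Mcm3 and Pcna by 0.40 and 0.43. The proliferation marker Mki67 differed by 0.30 (SE 0.25) and exceeded background on 0 control arrays and 3 a3a6KO arrays. Of the 37 genes 0 passed over all genes and 1, Kif20a, passed adjusted over the list alone (adjusted p = 0.0235). Camera called the list higher (adjusted p = 0.0129), lost at adjusted p = 0.779 with an estimated correlation, and lost without control 4 (0.0864), a3a6KO 2 (0.203) or a3a6KO 4 (0.136). The list score gave an exact permutation p of 0.114.

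Targets of p53, the transcription factor that answers DNA damage, were lower in 22 of 33 members with a mean of -0.14, which did not pass camera (adjusted p = 0.176) and was -0.062 without a3a6KO 2. Dcxr differed by -0.66, the antiproliferative gene Btg2 by -0.60, Plk3 by -0.51 and Ephx1 by -0.68. The cell cycle inhibitor gene Cdkn1a differed by -0.21 (SE 0.334) and Mdm2, whose product degrades p53, by 0.22 (SE 0.257). Of the list 0 genes passed over all genes and 0 adjusted over the list alone, and the score gave an exact permutation p of 0.0857. Background was exceeded on no array by 22 of the 33 members.

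Genes of the machinery that ties integrins to the cytoskeleton were higher in 17 of 26 members, with a mean of 0.11 that did not pass (camera adjusted p = 0.176). Tns3 differed by 0.48, Parvb by 0.67, the kindlin gene Fermt1 by 0.48 and the actinin gene Actn1 by 0.56, and 0 genes passed over all genes or adjusted over the list alone. Parvb exceeded background on 0 arrays and Tns3 on 0 control arrays. The list was called higher only without control 4 (mean 0.20, adjusted p = 0.0357). The other integrin subunits were higher in 14 of 22 members with a mean of -0.02 and a median of 0.04, so the mean opposed the direction of the test (camera adjusted p = 0.92), and 0 passed either way. Itgb8 differed by 0.46, Itga9 by -0.71 and Itga2 by -0.52, but these genes exceeded background on 0 arrays. In all, 18 of the 22 subunits exceeded it on no array. Laminin and basement membrane genes were higher in 10 of 18 members (mean -0.0024 against a median of 0.02 and a test direction of higher, camera adjusted p = 0.92), with Col4a5 at -0.41 and Nid2 at 0.39 and 0 passing either way. Of these 18 genes, 14 exceeded background on no array, Col4a5 and Nid2 among them.

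Markers of basal and myoepithelial cells, the outer layer of the mammary epithelium, were lower in a3a6KO in 19 of 20 members, with a mean of -0.73 but unevenly between samples. The mean was -0.45 without control 4 and -1.11 without a3a6KO 3. The keratin gene Krt14, above background on every array, was at 9.36 ± 1.48 in control and 7.76 ± 0.89 in a3a6KO (SD, n = 4), a difference of -1.60 (SE 0.707). Krt5 differed by -2.54, the myosin light chain gene Myl9 by -1.06 and the transcription factor gene Trp63 by -2.43. Of the 20 genes 3 exceeded background on every array, and Trp63 did so on 1 array, so its difference was measured near background. List scores were -0.21, 0.75, -0.30 and 1.23 in control 1 to 4 and -0.81, -0.77, 0.75 and -0.64 in a3a6KO 1 to 4, with an exact permutation p of 0.20. Of the list 0 genes passed over all genes and 0 adjusted over the list alone (smallest adjusted p = 0.0808). Camera called it lower (adjusted p = 0.00158), lost at adjusted p = 0.792 with an estimated correlation, without control 4 (0.180) and without a3a6KO 2 (0.0740).

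Keratins and other genes of squamous stress were lower in 10 of 12 members (mean -0.86), with Krt16 at -2.26, Sprr1a at -1.92, Sfn at -0.64 and Krt23 at 0.74. Camera called the list lower (adjusted p = 0.0333), lost at adjusted p = 0.792 with an estimated correlation, and 0 genes passed over all genes or adjusted over the list alone. The score stood at 1.83 in control 2 and 0.98 in control 3 and between -0.69 and 0.05 in the other 6 samples, and without these 2 controls the mean was 0.11. The call was lost without control 2 alone (mean -0.40, 0.587), control 3 alone (0.0962), a3a6KO 1 (0.0698) or a3a6KO 2 (0.150).

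Luminal identity genes were higher in 10 of 15 members (mean 0.04, camera adjusted p = 0.791, exact permutation p = 0.60). The luminal keratin gene Krt8 was at 10.4 ± 0.19 in control and 10.5 ± 0.14 in a3a6KO, and Muc1, of the smallest p in the list, differed by -0.74 (SE 0.256), Cldn3 by 0.24, Cdh1 by 0.18 and Cldn7 by 0.13. Markers of endothelial cells (mean 0.06), fibroblasts (-0.0025), leukocytes (-0.12) and adipocytes (0.03) did not pass camera, with adjusted p of 0.834, 0.813, 0.532 and 0.873. Of these markers, 7 of 14 endothelial, 11 of 14 fibroblast, 16 of 18 leukocyte and 7 of 9 adipocyte genes exceeded background on no array. A change in them could therefore be missed. In all 5 lists 0 genes passed over all genes and 0 adjusted over the list alone. The endothelial score was highest in control 4 (1.27) and a3a6KO 3 (0.98), and without control 4 the endothelial list was called higher in a3a6KO (mean 0.49, adjusted p = 0.0316). Among fibroblast genes, Col1a2 differed by 0.61 and Col3a1 by 0.87, while Dcn differed by -0.98. Col1a2 and Col3a1 exceeded background on 0 arrays. The mean and the median of the fibroblast list, both below 0, opposed the direction of its test.

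Interferon response genes were lower in 16 of 22 members (mean -0.29), although 16 of the 22 exceeded background on no array, with Oasl1 at -0.85, the transcription factor genes Irf1 at -0.74 and Irf7 at -1.05, and Bst2 at -0.65. Camera called the list lower (adjusted p = 0.0419), lost at adjusted p = 0.779 with an estimated correlation, and 0 genes passed over all genes or adjusted over the list alone. Its score was high in control 1 (0.59) and control 4 (0.34) alone, and the call was lost without control 1 (mean -0.14, 0.573), control 4 (0.0999), a3a6KO 1 (0.114), a3a6KO 2 (0.0740) or a3a6KO 4 (0.136), and with dim genes left out (0.164). In all, camera called 6 of 30 lists, 5 lower and 1 higher, and 0 of these calls held with an estimated correlation or in directional fry. All 6 lists passed by rank among random lists (adjusted p of 0.0020 to 0.0094), a test that takes no account of correlation between members.

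**Figure D3:**
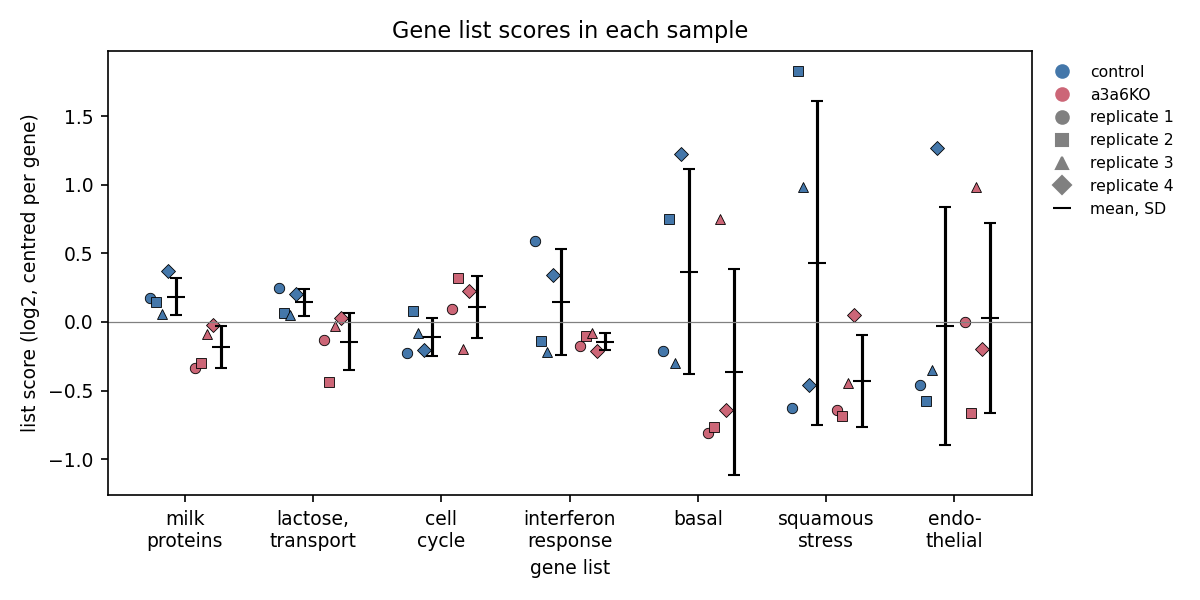
Mean centred log2 score (y axis) of 7 gene lists (x axis) in each sample, with 1 point per sample, its shape giving the replicate, and black bars for the group mean and SD. Milk protein scores of the a3a6KO samples (-0.33 to -0.02) lie below those of the controls (0.06 to 0.37), while basal and endothelial scores spread widely within both groups.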

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

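The tests of dilution by other cell types, of both relations between basal markers, and the counts over splits for the milk protein score and for genes past the threshold were chosen only after the result was seen.

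Milk protein genes were lower in a3a6KO in 14 of 14 members, and 1 of 35 splits of the 8 samples, the real one, gave a score difference as large (0.37 in size, highest other 0.331), a share that follows from the groups not overlapping. With 8 samples the exact p cannot fall below 0.0286. Adjusted over the 30 lists (0.429), it could have passed only if many lists reached that value, so the adjusted p decides nothing. The exact p was 0.0571 without control 1 or control 4, and 30 lists were examined, so chance is not excluded. Dilution of the a3a6KO samples by cells without luminal identity genes would lower these genes alike. Yet the luminal identity score minus the milk protein score was higher in a3a6KO by 0.463 (exact permutation p = 0.0286, the smallest possible). That p rests in part on the milk protein score, which had prompted the test. The luminal score alone, taken without Muc1, which both lists hold, was higher by 0.09 (exact permutation p = 0.286). These values argue against dilution by such cells only. A different mix of luminal cell types need not lower these genes, so it stays open. Poorer RNA or amplification in a3a6KO cannot be told apart from the genotype, because the area that separates exon from intron control sets differed by -0.0050 (exact permutation p = 0.514) and 4 arrays a group leave both directions possible. An effect of the genotype on milk genes stays open as a hypothesis. Camera called the lactose and transport list lower (adjusted p = 0.00901), though not with an estimated correlation (adjusted p = 0.779). The milk lipid and the prolactin and Stat5 lists did not pass camera (adjusted p = 0.438 and 0.532). The 4 a3a6KO samples are too few to relate milk scores (-0.33, -0.30, -0.09 and -0.02) to Itga6 (5.95, 3.65, 8.21 and 7.85).

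Basal markers were uneven between samples, with basal keratin scores of -0.64, 2.04, 1.09 and 0.57 in control 1 to 4 and -1.15, -1.42, -0.12 and -0.37 in a3a6KO 1 to 4 (exact permutation p = 0.0857), and with high levels of Krt14 (9.36 ± 1.48 in control and 7.76 ± 0.89 in a3a6KO) and Acta2 (8.70 ± 1.25 and 8.14 ± 1.19). Basal cells carried over in the sort, which the luminal gate should remove, would raise keratin and contractile markers together, but over 8 samples Pearson's r was 0.278 (permutation p = 0.503) and Spearman's rho 0.405 (permutation p = 0.326), and r was 0.385 without control 4 and a3a6KO 3, the farthest samples on the contractile score. Vascular cells, which that gate should remove as well, could account for the contractile markers, since their score correlated with the endothelial score at r = 0.790 (permutation p = 0.0321, adjusted over 2 relations 0.0642), but rho was 0.262 (permutation p = 0.534) and r became -0.659 without control 4 and a3a6KO 3, so the relation rests on those 2 samples. High contractile scores lay in 1 sample of each group, control 4 (2.20) and a3a6KO 3 (1.78), against -1.26 to 0.27 in the others. A difference between the groups, for which the contractile score gave an exact permutation p of 0.514, would not by itself produce that spread. As deviations from group means, contractile and endothelial scores correlated at r = 0.833, untested and with the same 2 samples included. With 8 samples neither source is settled. For the keratin markers, basal cells carried over cannot be told apart from an effect of the genotype.

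The real split gave 0 genes past the adjusted threshold, which all 35 splits reach by construction (highest other 2), so that count of splits decides nothing. At an unadjusted p under 0.05, 10 of 35 splits gave as many genes (1000, highest other 1123). As many lists were called by camera in 10 of 35 splits (6, highest other 11), so chance cannot be excluded for the number of called lists.

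A sample stood far from the other 3 of its group in 20 of 334 groups examined, against 16.7 by chance, in 13 genes and 7 list scores. In control samples these were Mpp1 at 5.20 in control 1, Col1a2 at 3.48 in control 2, and Itgb4 at 3.26, Sox10 at 6.99 and Tns3 at 5.39 in control 3, each below the others. Control 4 stood above the other controls for Eng (7.69) and Irf7 (4.96), for the endothelial score (1.27) and for the adhesion machinery score (0.20). Among a3a6KO samples, Csn2 was low in a3a6KO 1 (12.24 against 12.44 to 12.47), where Slc6a14 was high (3.43), and Ephx1 was low in a3a6KO 4 (4.41). In a3a6KO 2, Ctnnd1 (6.29) and the p53 target score (-0.29) were low and the Notch, Wnt and Hippo score (0.17) was high. In a3a6KO 3, Prpsap1 (6.59), the basal score (0.75) and the basement membrane score (0.61) were high, and Zfp36 (10.19) and the apoptosis score (-0.15) were low.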

How the results depend on the processing

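The fits without samples of high marker scores and those with a marker score as a covariate were chosen after seeing the data, as was the milk protein score without its 4 brightest casein genes (-0.44, exact p = 0.0286). All 20 alternative limma fits called 0 genes, with or without the minimum fold, and leaving out 1 sample gave 929 to 1061 genes at an unadjusted p under 0.05. With dim genes left out, that count was 658 of 12591 genes, since fewer were tested. Over 418 alternatives, the 22 genes named for their smallest p or by fixed names kept their side of the threshold over all genes, and 5 of them changed sign in 11 alternatives. Itga3 (-1.61 to -0.98) and Itga6 (-3.06 to -1.54) kept their calls over the 2 genes alone whichever sample was left out. Without control 2 and 3, Itga6 was -2.40 (adjusted p = 0.0783) with fewer samples in the fit, and the squamous stress list turned to 0.11. With the basal keratin score as a covariate, Itga3 was -1.30 (adjusted p = 0.138), Itga6 -1.31 (0.278), 3 lists were called and the squamous list turned to 0.41. That score itself differed between the groups by -1.53, so this fit cannot separate it from the genotype, and the cause was not tested. The called lists numbered 0 with an estimated correlation, 0 with directional fry and 1, luminal progenitor, with mixed fry. Under these 3 tests the milk protein list (-0.37) gave adjusted p of 0.779, 0.292 and 0.0679, and the cell cycle list (0.22) 0.779, 0.698 and 0.639. By rank among random lists, which takes no account of correlation between members, the milk protein (adjusted p = 0.0020) and cell cycle (0.0090) lists passed. So did the other lists called by camera with all samples, and the involution list. Camera's preset assumes members that hardly correlate, while the estimate was 0.281 for milk proteins and 0.101 for cell cycle. Leaving out 1 sample gave 1 (without a3a6KO 2) to 7 called lists. It moved the milk protein list between -0.42 and -0.31, always called by camera, the cell cycle list between 0.15 and 0.32, the milk lipid list between -0.218 and -0.042 and the adhesion machinery list between 0.07 and 0.20. The exact p of the milk protein score was 0.0571 without control 1 or control 4. Of 552 alternatives of the other lists, 512 kept their side of the threshold, some with a change of sign while not called, 29 lost a call without turning, 9 gained one, and 2, the squamous list above, turned and lost it. Leaving out single samples changed the sign of the means of the endothelial, adipocyte, fibroblast, basement membrane, integrin subunit, luminal identity, hormone-sensing, apoptosis, cytokine, immediate early and ribosomal lists, none of them called with all samples. Replicate numbers did not pair the samples, since deviations of same-numbered samples correlated at 0.032, 0.039, -0.053 and -0.061. With the replicate number as a block, 0 genes were called, 1003 had an unadjusted p under 0.05, the involution list was called (-0.22, adjusted p = 0.0467) and the interferon list was not (-0.29, 0.0742), and not every sample correlated best with its own number. Signal over background limits dim genes, since at most 3229 genes of an array exceeded the 95th percentile of its intron control sets.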

Other observations

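The fits without both controls or with a covariate were chosen after seeing the data. The clock gene lists were chosen after Nr1d1 had been seen among the genes of smallest p, and the test of those above background was chosen after their values had been seen.

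Luminal progenitor genes differed in both directions in a3a6KO, 6 higher and 10 lower of 16 (mean -0.13). The retinaldehyde dehydrogenase gene Aldh1a3 differed by 1.33 (SE 0.43) and Sox10 by 0.44, while Ltf, which encodes lactoferrin, differed by -1.02 and the receptor gene Notch1 by -0.66. Aldh1a3 exceeded background on 0 control arrays, Ltf on 0 a3a6KO arrays and Notch1 on 0 arrays, so these sizes are uncertain. Sox10 exceeded it on all 8 arrays, but control 3 (6.99) lay below the other controls (7.56 to 7.58). Mixed fry, which asks for change in either direction, gave this list an adjusted p of 0.0129, the only list it called among 30, while camera gave 0.532, and 0 genes passed over all genes or adjusted over the list alone (smallest adjusted p = 0.155). Hormone-sensing luminal genes were lower in 7 of 13 members (mean -0.11, but 0.07 without control 3 and -0.30 without a3a6KO 4, camera adjusted p = 0.813), with Cxcl15 at -0.83. Of these 13 genes, 9 exceeded background on no array. Involution and Stat3 genes, which mark the regression of the gland after weaning, were lower in 17 of 24 members (mean -0.22, camera adjusted p = 0.0564), and were called lower without control 2 (0.0291), control 3 (0.0257), both (0.0028) or a3a6KO 3 (0.0221), with the endothelial score as a covariate (0.0280) and by rank among random lists (0.0060). The lists that camera called with all samples passed by that rank too, and it takes no account of correlation between members. With an estimated correlation the involution list had an adjusted p of 0.779, with directional fry 0.677, and the exact permutation p of its score was 0.114. Among the involution genes were Saa2 at -0.93, Timp1 at 0.89, Cp at -0.53 and Saa1 at -1.08. Inflammatory cytokine genes were lower in 14 of 21 members (mean -0.09, camera adjusted p = 0.379), with the adhesion molecule gene Icam1 at -1.16, Il33 at -0.48 and Tnf at -1.39. Il33 exceeded background on 0 arrays. In these 3 lists 0 genes passed over all genes and 0 adjusted over the list alone.

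Apoptosis regulators were balanced, 9 higher and 10 lower of 19 (mean -0.0037, camera adjusted p = 0.71), with the inhibitor gene Birc3 at -0.76 and Casp12 at 0.99. Junction and polarity genes had a mean of -0.12 (camera adjusted p = 0.92), with Llgl2 at -1.13 and Crb3 at 0.64. The unfolded protein and integrated stress list had a mean of -0.09 (camera adjusted p = 0.501), with the asparagine synthetase gene Asns at -0.94 and Xbp1 at -0.40. Oxidative phosphorylation genes had a mean of -0.06 (camera adjusted p = 0.532), with the complex I genes Ndufv2 at -0.87 and Ndufb8 at -0.60. Means were -0.13 for oxidative stress genes (camera adjusted p = 0.55), 0.01 for ribosomal protein genes (0.83), 0.10 for translation and Myc growth genes (0.532), 0.06 for Notch, Wnt and Hippo targets (0.813) and -0.06 for the immediate early genes that dissociation of tissue can induce (0.71). Of the Notch, Wnt and Hippo targets, 13 of 16 exceeded background on no array. Casp12, Llgl2 and Ndufv2 exceeded it on 0 arrays, Crb3 on 0 control arrays and Ndufb8 on 0 a3a6KO arrays. In all 9 lists 0 genes passed over all genes and 0 adjusted over the list alone. Of 2634 unnamed transcript sets, 0 were called by limma and 139 had an unadjusted p under 0.05.

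Nr1d1 was lower in all 4 a3a6KO samples (-1.52, adjusted p = 0.631), and so was Bhlhe40, another clock repressor gene (-1.34, adjusted p = 0.743), which was singled out after its values were seen. A hypothesis was that tissue of both groups was taken at different phases of the daily clock. The score of 9 clock genes taken as in phase with Nr1d1, Per genes among them, minus that of 4 genes taken as in antiphase differed by -0.0708 (exact permutation p = 0.543). Whether these genes peak at the same time as Nr1d1 was not checked here. Of the 9 genes taken as in phase, 6 exceeded background on 0 arrays. The other 3, Hlf (0.01), Per1 (-0.19) and Bhlhe41 (0.18), had a score difference of 0.00 (95% interval -0.214 to 0.214). These 3 genes were thus not lowered about as far as Nr1d1 and Bhlhe40. How far a difference in phase would move them is not known here, so they do not decide the question. A difference in phase cannot be told apart from none, since the difference over all 13 genes lay within the spread between samples.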
